A study of Mus musculus with 29 samples.

How the data were processed

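Expression was measured in 29 mouse samples, 24 primary abdominal tumours and 5 bone marrow samples, of TH-MYCN animals labelled as strain 129X1/SvJ. Per the labels' protocols, total RNA was extracted with Trizol, and biotinylated cRNA was made with a two-cycle protocol from 100 ng. The deposited values are on a log2 scale, and the authors made them with RMA (background correction, quantile normalization and summary of probes) in Partek 6.6, per the submitters' processing notes. Whether all 29 arrays were normalized together is not given in the sources used here. RMA compresses low signals, and quantile normalization removes shifts common to most genes. Arrays have no read depth, so their number limits the precision.

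The table held 45101 probe sets, of which 64 were array controls. In the platform annotation 34945 probe sets had 1 gene symbol, 932 several and 9160, controls aside, none listed. Symbols were updated or kept through the Entrez ID for 34741 of them with a gene table of assembly GRCm38.p6, which served only for names and for the order of genes. The probe set with the highest mean over all arrays stood for each of 18193 genes, 9010 of which had more than 1. No values were filtered. Human MYCN was not analysed here.

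Groups came from the genotype and tissue labels. Samples were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05) within tumours, within marrow, and in a 4-group model for tissue and interaction. The 35 gene lists were tested by exact permutation of list means in tumours and between tissues, and by camera with a preset correlation of 0.01 in marrow, where a permutation of 2 against 3 samples cannot go under 0.1. Genes near Casp8 were the 40 measured genes on each side. Figures were drawn with matplotlib 3.10.9.

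The tests, gene lists, the alternatives not named below as added and the rule for named genes were fixed before the data were examined. The rule took the 12 genes of largest log2 difference in each direction among those called, or, with fewer than 5 calls in a direction, the 6 of smallest p as values. It took the 5 of smallest p for the interaction, always Casp8, Mycn, Th, Dbh and another gene that is not reported here, and the 4 members of smallest p of each list described. Xist and Y-linked genes were described together, and unnamed predicted loci were passed over. The fits were tested on simulated data of 18193 genes, 200 of them changed in each of 5 runs. Alternatives changed the probe set rule, a mean log2 filter of 5, the normalization, array weights, the variance model, covariates and the samples included.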

Results

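The series profiled gene expression in mice carrying the TH-MYCN transgene, which drives MYCN in the sympathoadrenal lineage and gives rise to neuroblastoma, a tumour of that lineage. Animals were either wild type for caspase-8, an initiator protease of death receptor signalling, or deficient for it. RNA from 24 primary abdominal tumours (7 wild type, 17 deficient) and from 5 bone marrow samples (2 wild type, 3 deficient) was hybridised to a mouse 3' expression array, 1 array per sample. The values were log2 expression after RMA and ranged from 1.87 to 14.4. No pair of arrays held identical values. Correlations across probe sets within a group ranged from 0.972 to 0.993, and those between a tumour and a marrow sample from 0.806 to 0.865. The labels do not say whether each sample came from its own animal, so p-values measure the spread between these samples. The number of arrays limits the precision, above all in bone marrow.

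The targeted gene was examined first. Casp8 signal in tumours was 5.88 ± 0.57 (SD, n = 7) in wild type and 5.62 ± 0.44 (SD, n = 17) in deficient samples, a log2 difference of -0.26 (SE 0.20, limma adjusted p = 0.9997). It was -0.085 without wild type tumour 1, and -0.40 and -0.15 in the lower and higher series of numbers in the sample titles. In bone marrow it was 9.46 ± 0.23 (SD, n = 2) and 9.14 ± 0.12 (SD, n = 3), a difference of -0.32 (SE 0.19) that was -0.16 without wild type marrow 2 and -0.49 without wild type marrow 1. The labels do not give the deleted part of the gene, and a probe set outside that part does not check the genotype. Mycn, the mouse counterpart of the transgene, was at 7.58 ± 0.17 in wild type and 7.54 ± 0.18 in deficient tumours, and its difference turned sign without wild type tumour 2, at 0.0056. Th, which encodes tyrosine hydroxylase, and Dbh, which encodes dopamine beta-hydroxylase, both enzymes of catecholamine synthesis, differed by -0.42 (SE 0.31) and -0.19 (SE 0.25) between deficient and wild type tumours, within the spread between samples. In the lower title series both turned sign, at 0.13 and 0.16, as did Mycn, at 0.038, and in the higher series Th was at -0.82 and Dbh at -0.45. Dbh ran from -0.49 without wild type tumour 1 to -0.014 without wild type tumour 6, and was at -0.038 without wild type tumour 2.

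The first comparison asked which genes differ between caspase-8 deficient and wild type tumours. None of the 18193 genes passed an adjusted p of 0.05 in limma, and 583 had an unadjusted p under 0.05, against 909.7 expected by chance. The genes of smallest p are given as values and not as calls. Among those with higher values in deficient tumours, Cdc25b, a phosphatase that activates cyclin-dependent kinases, differed by 0.34 (SE 0.08), Layn by 0.24, Pcdh1 by 0.35, Tfpi2, a serine protease inhibitor, by 0.96 (SE 0.26), Gtse1 by 0.30 and Ntrk2, the receptor for brain-derived neurotrophic factor, by 0.36. Among those with lower values, Ccdc149 differed by -0.38 (SE 0.09), Zim3 by -0.19, Ly6f by -0.24, Grap2 by -0.32, Mixl1 by -0.23 and a variable segment of the immunoglobulin kappa chain by -0.42. In the lower title series Cdc25b was at 0.13, Tfpi2 at 0.43, Gtse1 at 0.15, Pcdh1 at 0.23, Ntrk2 at 0.22 and Mixl1 at -0.14, and with the mean of a gene's probe sets Ntrk2 was at 0.012 and Layn at 0.11. The median 95% interval reached 0.18 to each side, and 98.2% of genes had an interval that excluded a 2-fold difference. That share covers 1 probe set per gene, with genes of low signal included. Low signal compresses differences, so an interval there can exclude a 2-fold difference in signal but not in transcript level. In simulated data with the spread of these tumours, 93.6% of the 50 genes per run given a log2 change of 1 were called, and 78.4% of those given 0.5. Each run held 200 changed genes of sizes up to 3, with noise drawn independently for each gene, which eases the adjusted threshold. Changes in only a few genes face a stricter one, so these shares do not show that such changes are absent.

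Endothelial markers had the smallest p of the 35 gene lists in tumours, without passing the adjusted test. All 20 measured endothelial markers had higher mean values in deficient tumours and 9 had an unadjusted p under 0.05, while 0 passed either over all genes or adjusted over the list alone. The list mean was 5.83 ± 0.40 (SD, n = 7) in wild type and 6.25 ± 0.39 (SD, n = 17) in deficient tumours, a difference of 0.42, with an exact permutation p of 0.0253 that became 0.702 after adjustment over 35 lists. Ramp2, a co-receptor for adrenomedullin, differed by 0.50 (SE 0.15), the sialomucin Emcn by 0.68 (SE 0.24), the receptor tyrosine kinase Tie1 by 0.41 and Mmrn2 by 0.64. The 3' minus 5' signal of the array's control probe sets, a measure of RNA quality, was 0.616 ± 0.145 (SD, n = 7) in wild type and 0.761 ± 0.175 (SD, n = 17) in deficient tumours (exact permutation p = 0.0656). Without wild type tumour 5, which had the lowest endothelial mean of the 24 tumours, 5.00, the list difference was 0.28 and that of Mmrn2 0.39. The titles number the samples in a lower and a higher series, and within these, an analysis added after the data were seen, it was 0.12 (3 against 7 tumours, exact permutation p = 0.642) and 0.64 (4 against 10 tumours, exact permutation p = 0.0180, adjusted p = 0.175).

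Genes of vessel walls, interstitial matrix and fat had higher mean values in deficient tumours without passing the test. The pericyte and smooth muscle list differed by 0.32 (exact permutation p = 0.0916), with Notch3 at 0.45, Mcam at 0.42, Lmod1 at 0.18 and Rgs5 at 0.55. The basement membrane list differed by 0.24 (exact permutation p = 0.0836), with the collagen chains Col4a1 at 0.63, Col18a1 at 0.54 and Col4a2 at 0.52 and the linker Nid1 at 0.55. The interstitial collagen and matrix list differed by 0.33, with 22 of 23 members higher (exact permutation p = 0.225), and the adipocyte list by 0.26, with 10 of 12 members higher (exact permutation p = 0.516). Without wild type tumour 5 the pericyte list was at 0.14, the basement membrane list at 0.12, the interstitial matrix list at 0.19, Rgs5 at 0.23, Col4a1 at 0.33, Col4a2 at 0.24 and Nid1 at 0.29, and without wild type tumour 1 the interstitial matrix list was at 0.58. The adipocyte list was at 0.096 without wild type tumour 5, 0.12 without wild type tumour 4, 0.16 without deficient tumour 3 and 0.53 without wild type tumour 1 (adipocyte markers list, tumours, deficient minus wild type), and at 0.021 and 0.45 in the lower and higher number series. In the 10 tumours of the lower number series, taken alone, the pericyte list was at -0.17, the interstitial matrix list at -0.14 and the basement membrane list at -0.058, and Col4a1, Col18a1, Col4a2, Nid1, Notch3 and Rgs5 also had the opposite sign. In the higher series the pericyte list was at 0.67 (exact permutation p = 0.00999, adjusted p = 0.175) and the basement membrane list at 0.47 (exact permutation p = 0.0270, adjusted p = 0.189). The hypoxia and glycolysis list differed by -0.23 (exact permutation p = 0.0655), with 17 of 18 members lower, among them Bnip3 at -0.40, Ankrd37 at -0.38, Egln3 at -0.69 and Adm at -0.63. Bnip3 was at -0.23 without wild type tumour 6, and Adm at -1.09 without wild type tumour 1. In the lower series that list was at 0.079 and these 4 genes turned sign, and in the higher series it was at -0.45, with an exact permutation p of 0.000999, the smallest that 1001 splits can give, and an adjusted p of 0.0350 over 35 lists in a subset examined after the data were seen. Over the alternatives for the hypoxia and glycolysis genes list, tumours, deficient minus wild type, adjusted p ran from 7.15e-06 with camera at a preset correlation to 0.954 without wild type tumour 5. Whether the series differ was not tested. The 26 apoptosis and death receptor genes differed by -0.022 as a list, which ran from -0.047 without wild type tumour 2 to 0.038 without wild type tumour 1 and was at -0.096 and 0.032 in the lower and higher series. Of its members, Diablo was at 0.15, Bid at -0.16, Cyld at -0.18 and Casp9 at -0.13, the last of which was at -0.058 without wild type tumour 6, -0.21 without wild type tumour 7 and -0.022 with the mean of probe sets. The sympathoadrenal list, at -0.043, ran from -0.12 without wild type tumour 1 to -0.0017 without wild type tumour 2, and was at 0.070 and -0.12 in the lower and higher series. The sign of the neuronal differentiation genes list, tumours, deficient minus wild type, at 0.015, turned without wild type tumour 1, at -0.022, and without deficient tumour 9, at -0.0013, and the value was 0.044 without wild type tumour 2. Chromaffin markers differed by -0.30, with 1 of 10 members higher (exact permutation p = 0.153), and were at -0.17 without wild type tumour 6 and at 0.18 and -0.64 in the lower and higher series. Erythroid markers differed by 0.26, with 7 of 16 members higher and a median member difference of -0.021 (exact permutation p = 0.108), and were at 0.050 and 0.41 in these series. Over all tumours none of the 35 lists passed an adjusted p of 0.05 in the permutation test and 1 had an unadjusted p under 0.05, while camera with a preset correlation, which assumes nearly independent genes, called 15 and camera with an estimated correlation called 0.

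**Figure D1:**
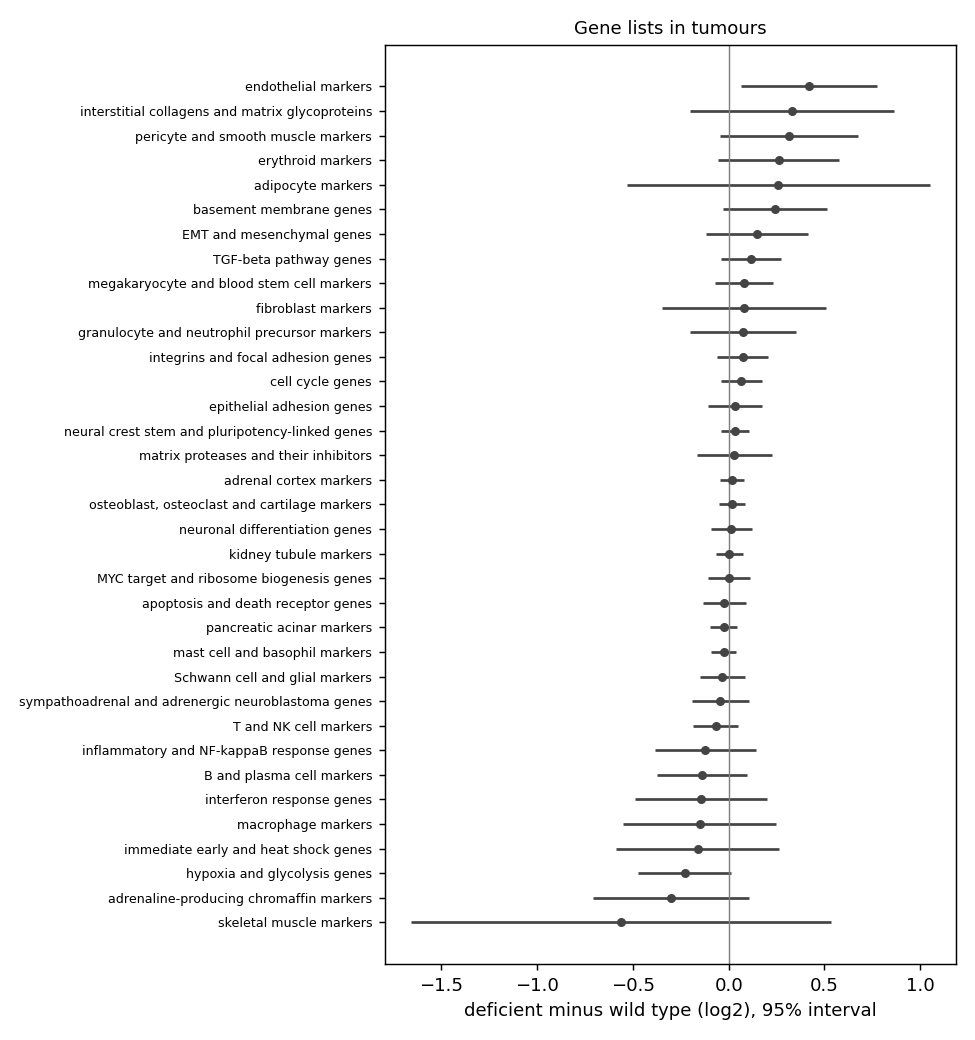
Difference of each list mean between 17 deficient and 7 wild type tumours (horizontal axis, log2), with the 95% limma interval as bars. The endothelial list lies highest, at 0.42, and the skeletal muscle markers list, tumours, deficient minus wild type, lowest, at -0.56, which was -0.11 without wild type tumour 3, -0.27 without wild type tumour 7, -1.14 and -0.15 in the lower and higher title series, and 0.050 without the 3 tumours with a mean of that list above 6 and wild type tumour 1.

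Testing each of 45037 probe sets, in place of 1 per gene, gave 1 call in tumours, a probe set of Lancl1, which encodes a glutathione-binding LanC-like protein. It was named after its value was seen. Its signal was 6.55 ± 0.25 (SD, n = 7) in wild type and 5.51 ± 0.28 (SD, n = 17) in deficient tumours, a log2 difference of -1.04 (SE 0.12, limma adjusted p = 0.000124). The lowest wild type tumour, at 6.19, lay above the highest deficient one, at 6.04, and the exact permutation p of 2.89e-06 is the smallest the 346104 splits can give. The gene's other probe set, which was brighter and stood for the gene in the gene-level fit, was at 9.69 ± 0.11 in wild type and 9.88 ± 0.19 in deficient tumours, a difference of 0.19 (SE 0.08). Within the lower and higher title number series the difference of the first probe set was -0.995 and -1.07, with adjusted p of 0.9999 and 0.0867 in those smaller fits. In marrow the first probe set was at 4.31 and 4.30.

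**Figure D2:**
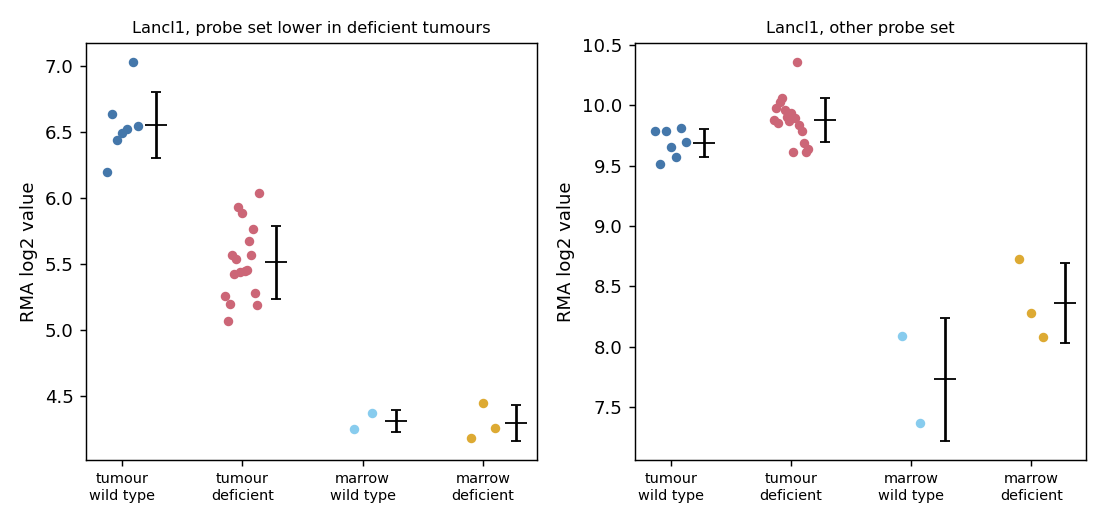
RMA log2 values of both Lancl1 probe sets (vertical axes) in the 29 samples by group. Points are samples, and bars give mean and SD. The 7 wild type tumours lie at or above 6.19 and the 17 deficient ones at or below 6.04 in the left panel, and the groups overlap in the right panel.

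The positions of genes on chromosomes were compared because a targeted allele brings neighbouring sequence with it. No gene was called in tumours at gene level, so the planned test of the 80 measured genes nearest to Casp8 held 0 calls and has no information. At an unadjusted p under 0.05 it held 1 of 80 genes, 1.25%, against 3.19% of other genes (Fisher's exact test, p = 0.523). Lancl1 lies on the same chromosome as Casp8, chromosome 1, 55 places away in the order of measured genes and so outside the 40 on each side in the planned test.

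The second comparison asked the same of bone marrow. The 4 genes called were Xist, the RNA that silences an X chromosome in female cells, which was higher by 6.24 (SE 0.34) in deficient marrow, and the Y-linked genes Eif2s3y, Kdm5d and Uty, which were lower there by 6.65, 3.74 and 2.91. In deficient marrow these 3 were at 2.68, 2.71 and 2.99, near the array's lowest value, where low signal compresses a difference. With the mean of probe sets the value of Eif2s3y, marrow, deficient minus wild type, was -3.43, and Kdm5d and Uty, at -1.35 and -1.75, did not pass. Both wild type marrow samples had low Xist and high Y-linked signal, and all 3 deficient ones the reverse, so the marrow groups were split by these genes as well as by genotype. Among tumours, Xist was high in 3 of 7 wild type and in 10 of 17 deficient samples. Without these genes limma called 0, with a lowest adjusted p of 0.313, and 737 of all genes had an unadjusted p under 0.05. With 2 against 3 samples, 16.8% of simulated genes with a log2 change of 1 and 76.8% of those with a change of 2 were called. These runs likewise held 200 changed genes, which eases the adjusted threshold.

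The remaining marrow genes are given as values. Those of smallest p with higher values in deficient marrow were Cd59a, a complement inhibitor, at 2.14 (SE 0.29), Apoc2 at 1.44, Gpc4 at 1.25, Tac2 at 1.78, Ddx4 at 1.13 and Pcp4l1 at 1.07. Those with lower values were Vsig4, a macrophage complement receptor, at -1.03 (SE 0.19), Ttc9b at -1.03, Lix1 at -0.95, the collagenase Mmp13 at -2.02 (SE 0.43), Wfdc17 at -1.08 and the granule protease Gzma at -1.06. The lower group's mean was under 5 for 6 of these 12 genes (Apoc2, Ddx4, Pcp4l1, Vsig4, Ttc9b and Lix1), where low signal compresses a difference.

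By camera with a preset correlation, which assumes nearly independent genes, 10 of 35 lists shifted in deficient marrow, 8 up and 2 down. None of the 10 kept its call with an estimated correlation, where adjusted p ran from 0.699 to 0.772. B and plasma cell markers had the list difference of 0.51 (camera adjusted p = 0.000527, and adjusted p = 0.699 with an estimated correlation), with Mzb1 at 0.85, Jchain at 0.84, Ighm at 1.05 and Fcmr at 0.90. Fcmr was at 0.21 without wild type marrow 2, 0.58 without deficient marrow 1 and 1.58 without wild type marrow 1, and Ighm at 0.65 without deficient marrow 3 and 0.61 with the mean of probe sets. Megakaryocyte and blood stem cell markers differed by 0.31, with Vwf at 0.87, Clec1b at 0.47, Gata2 at 0.45 and Ppbp at 0.49. Without wild type marrow 1 Vwf was at 0.35, Gata2 at 0.24 and Ppbp at 0.16, and without wild type marrow 2 Vwf was at 1.40 and Ppbp at 0.82. Inflammatory genes differed by 0.28, with the chemokines Ccl3 at 0.89, Ccl4 at 0.52 and Cxcl10 at 0.79 and the antagonist Il1rn at 0.69. Ccl3 was at 0.59 without deficient marrow 2, Ccl4 at 0.34 without wild type marrow 1 and Il1rn at 0.37 without wild type marrow 2. Cell cycle genes differed by -0.16, with Aurkb at -0.43, Tyms at -0.36, Bub1 at -0.32 and Foxm1 at -0.35. With the mean of probe sets Bub1 turned sign, at 0.40, Tyms was at -0.20 and Foxm1 at -0.13. Without deficient marrow 3 Aurkb was at -0.26, Bub1 at -0.17 and Foxm1 at -0.21, without wild type marrow 2 Aurkb was at -0.27 and Tyms at -0.17, and without wild type marrow 1 Tyms was at -0.54 and Foxm1 at -0.20. MYC target and ribosome biogenesis genes differed by -0.13, with Wdr43 at -0.39, Polr1b at -0.34, Gnl3 at -0.26 and Shmt2 at -0.42. Polr1b was at -0.21 without wild type marrow 2, and Shmt2 at -0.23 without wild type marrow 1, -0.25 without deficient marrow 2 and -0.67 without deficient marrow 1. No member of these 5 lists passed limma, over all genes or adjusted over the list alone. The other 5 lists were T and NK cell markers at 0.19, granulocyte markers at 0.19, bone cell markers at 0.26, interferon response genes at 0.20 and immediate early genes at 0.61. In the last of these deficient marrow 3 stood at 8.99, and the other 4 samples between 7.12 and 7.56. Adjusted over the list alone, Gzma (T and NK cell), Mmp13 (matrix protease) and Elavl3 (neuronal, -0.79) passed with lower values and Oasl1 (interferon, 1.22) with a higher one, and none of these 4 passed over all genes. Without wild type marrow 2 camera called 6 lists, and without wild type marrow 1 the interferon and granulocyte lists turned sign. For the B and plasma cell markers list, marrow, deficient minus wild type, the value relative to other genes was 0.16 without wild type marrow 1, 0.19 without deficient marrow 2, 0.80 without deficient marrow 3 and 0.86 without wild type marrow 2, and camera called it each time. The other 9 lists each lost the call in at least 1 fit without a sample. Megakaryocyte markers were at 0.077 without wild type marrow 1 and 0.55 without wild type marrow 2, inflammatory genes at 0.083 without deficient marrow 3 and 0.44 without deficient marrow 1, and immediate early genes at 0.067 and 0.97 without these. Cell cycle genes were at -0.080 without wild type marrow 2 and MYC target genes at -0.080 without wild type marrow 1.

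Transcripts of the tumour lineage were looked for in each marrow sample. The mean of 20 sympathoadrenal genes was 4.42 and 4.34 in wild type marrow and 4.41, 4.52 and 4.45 in deficient marrow, against 9.65 ± 0.16 (SD, n = 24) in tumours. By arithmetic on the measured means, tumour RNA at 1% of a marrow sample would raise the list mean by 0.84 and at 0.1% by 0.14. The arithmetic takes wild type marrow as free of tumour RNA and signal as linear, while low signal is compressed, so it sets no detection limit. The highest deficient sample exceeded the wild type mean by 0.14, and the list did not pass camera (adjusted p = 0.378). In that sample, deficient marrow 2, 10 of the 20 genes lay above both wild type samples. Th, at 3.87 against 4.70 and 4.09, and Hand2, at 3.69 against 4.34 and 4.18, lay below both.

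The third comparison set tumours against bone marrow. The 13899 genes called by limma comprised 6218 higher and 7681 lower in tumours, and 5347 of them differed at least 2-fold. The median over all genes was -0.10, and differences are read relative to it. Agtr2, an angiotensin receptor, was higher by 9.76 (SE 0.12) on the log2 scale, the neurofilament genes Nefl and Nefm by 9.35 and 8.34, the granin Chgb by 8.79, the actin bundler Fscn1 by 8.63 and Stmn2 by 8.10. The transcription factors Isl1, Sox11 and Tfap2b were higher by 8.60, 8.22 and 7.95, the catecholamine enzyme Ddc by 8.10, the synaptic gene Snap25 by 8.01 and Cpe by 7.96. Th was higher by 6.80 (SE 0.34), Dbh by 2.03 (SE 0.27) and Mycn by 0.74 (SE 0.12). All of these genes but Dbh and Mycn had a marrow mean under 5, from 2.56 for Agtr2 to 4.22 for Th, and low signal compresses a difference. The values are fitted contrasts that weight both genotypes equally, so they can differ slightly from the difference of the tissue means. With the mean of a gene's probe sets Fscn1 was at 2.61, Ddc at 4.77, Snap25 at 5.16, Cpe at 3.45 and Mycn, which then did not pass, at 0.15.

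Genes of granulocytes and red cells were among those with the lowest values. The granule genes Ngp, Ltf, Lcn2, Olfm4 and Camp were lower in tumours, at -10.06, -9.54, -9.07, -8.91 and -8.82, as were the calprotectin genes S100a9 and S100a8 at -9.41 and -9.05, Prg2 of eosinophils at -9.44, Chil3 at -9.17 and Ifitm6 at -8.95. The erythroid genes Hemgn and Car1 were at -9.79 and -8.74. These 12 genes had tumour means between 2.83 and 4.94, so the sizes of their differences are likewise open to compression at low signal. Of the 13899 called genes, 6240 had a mean under 5 in the tissue where they were lower. Casp8 was lower in tumours, at -3.55 (SE 0.22).

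Of the 35 lists, 28 shifted by the exact permutation test, 9 up and 19 down in tumours. The smallest adjusted p, 1.73e-05, is that of the smallest p the 118755 splits can give. Of 20 sympathoadrenal genes, 18 were higher and 1 lower, with Hand2 at 7.27 and Eya1 at 6.94, and of 18 neuronal genes 17 were higher and 1 lower, with Ina at 6.85 and Elavl4 at 6.30. All 18 granulocyte markers were lower, with Mpo at -8.31 and Ctsg at -7.75, and 15 of 16 erythroid markers, with Rhag at -8.54, Klf1 at -7.70 and Rhd at -7.14. Of 21 interferon response genes 19 were lower, among them Usp18 at -3.56, Irf9 at -2.98, Ddx58 at -1.94 and Oasl1 at -1.80. Of 26 apoptosis and death receptor genes 22 were lower and 2 higher, with the death receptor Fas at -2.67 and Bcl2l1, Bak1 and Mcl1 at -2.56, -2.33 and -1.48. With the mean of probe sets Bcl2l1 was at -1.32, Bak1 at -1.28 and Hand2 at 3.29. Of 25 MYC target and ribosome biogenesis genes 20 were higher and 3 lower, with Srm at 2.11, Gnl3 at 1.36 and Eif4a1 at 1.08 against Tfrc, the transferrin receptor, at -2.22. Of 23 interstitial matrix genes 15 were higher and 3 lower, with Col3a1 at 4.17, Postn at 3.87 and Col1a1 at 2.33 against Thbs1 at -2.78. Of the members named here, Hand2, Eya1, Ina, Elavl4, Mpo, Ctsg, Rhag, Klf1, Rhd, Usp18, Ddx58, Oasl1, Fas, Bak1 and Postn also had a mean under 5 in the lower tissue. For these 8 lists the counts were the same adjusted over the list alone. With an estimated correlation the interferon, apoptosis, MYC target and interstitial matrix lists did not pass camera, with adjusted p of 0.414, 0.0728, 0.261 and 0.822. Of the 28 lists camera so kept 5, with adjusted p of 0.00244 for sympathoadrenal, 0.000436 for neuronal, 0.00797 for granulocyte, 0.0173 for erythroid and 0.0212 for mast cell genes.

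Lists of other cell types and programmes also differed between the tissues. Chromaffin markers were higher in tumours by 3.26, basement membrane genes by 1.34, pericyte markers by 1.16 and adipocyte markers by 0.88 (exact permutation, adjusted p = 0.0418). Megakaryocyte and blood stem cell markers were at -2.49, B and plasma cell markers at -2.42, mast cell markers at -2.38, T and NK cell markers at -1.39, inflammatory genes at -1.03, macrophage markers at -0.81 and bone cell markers at -0.73. With an estimated correlation camera gave adjusted p of 0.261 for chromaffin, 0.494 for basement membrane, 0.656 for pericyte, 0.870 for adipocyte, 0.133 for megakaryocyte, 0.215 for B cell, 0.130 for T and NK cell, 0.494 for inflammatory, 0.838 for macrophage and 0.215 for bone markers. Neural crest stem genes had a list mean higher by 0.082 (adjusted p = 0.0262, and adjusted p = 0.838 with an estimated correlation) but a median member difference of -0.084, and the sign turned with the mean of probe sets. Kidney tubule, pancreatic acinar and adrenal cortex markers also passed as lower in tumours (exact permutation, adjusted p = 1.73e-05, 3.10e-05 and 3.10e-05). Their means were 3.65, 4.12 and 4.54 in tumours and 3.96, 4.40 and 4.73 in marrow, all at low signal. With an estimated correlation camera gave them adjusted p of 0.414, 0.494 and 0.494. Small shifts at low signal thus also pass the permutation test, and their cause was not tested. Endothelial markers, at 0.29, and fibroblast markers, at 0.080, did not pass.

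**Figure D3:**
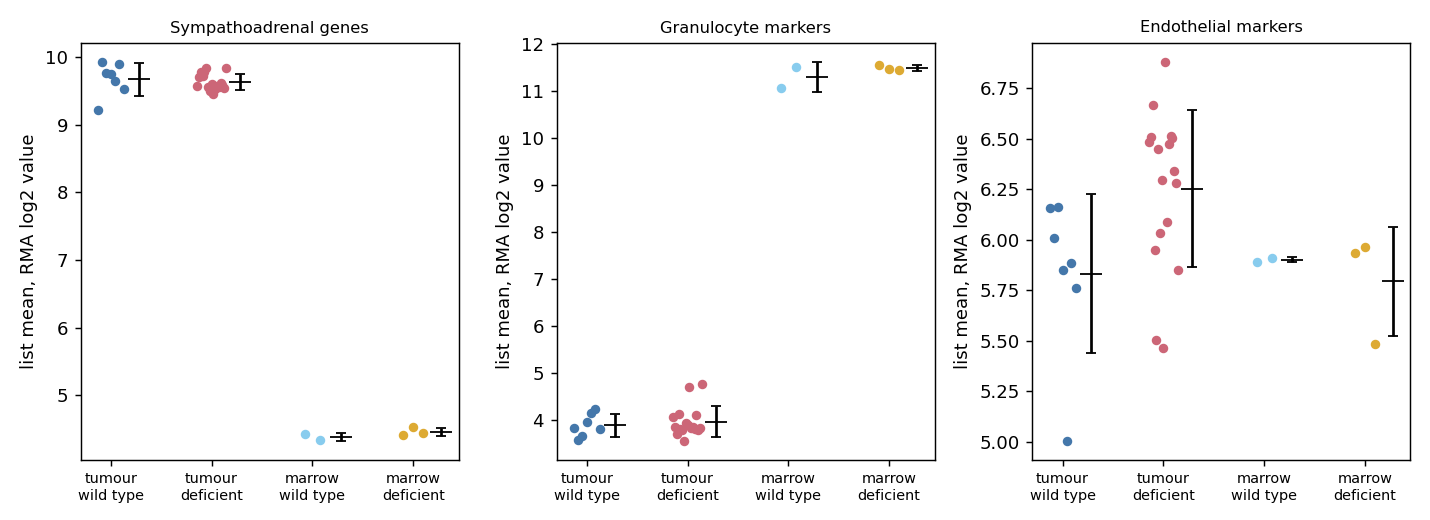
List means in each of the 29 samples (vertical axes, RMA log2) for sympathoadrenal genes, granulocyte markers and endothelial markers, by group. Points are samples, and bars give mean and SD. Sympathoadrenal means lie between 4.34 and 4.52 in the 5 marrow samples, and endothelial means average 5.83 in wild type and 6.25 in deficient tumours.

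The last comparison asked whether the genotype difference itself differs between tissues. In limma 58 genes passed, 35 with a more positive and 23 with a more negative difference in marrow. The 5 of smallest p were Ddx4, a germ cell RNA helicase, at 1.10 (SE 0.13), Cd59a at 2.10 (SE 0.26), Trgv4, a T cell receptor gamma segment, at -3.08 (SE 0.44), the sialomucin Podxl at -2.22 (SE 0.32) and Armcx2 at 0.94 (SE 0.14). In tumours 38 of the 58 genes had means under 5 in both genotypes, among them Ddx4 at 2.45 and 2.48 and Trgv4 at 2.95 and 2.95, near the lowest array value of 1.87. A genotype difference in tumours can go unseen at such signal, so for genes near that value the test largely restates the marrow difference. Wild type and deficient tumours were at 5.35 and 5.39 for Cd59a, 7.61 and 7.86 for Podxl and 11.17 and 11.14 for Armcx2. Casp8 differed by -0.066 (SE 0.44), Mycn by 0.16, Th by 0.13 and Dbh by 0.37. Without 1 sample Casp8 ran from -0.24 to 0.096, Mycn from -0.10 to 0.48, Th from -0.17 to 0.43 and Dbh from 0.19 to 0.67. With the mean of probe sets Trgv4 was at -1.72, Armcx2, which then did not pass, at 0.50 and Dbh at 0.077. The marrow groups also differed in Xist and Y-linked signal, so these differences cannot be assigned to genotype. None of the 58 passed in the limma fit of marrow alone, where 57 had an unadjusted p under 0.05, and the count moved to 32 without wild type marrow 1 and to 422 without wild type marrow 2.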

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

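The tests on RNA quality and on shared sex-biased expression over all 58 genes were set before their results were seen; the other tests in this part were chosen after.

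In the group of 7 wild type tumours, a sample is named where its gap to the nearest other exceeded 0.568 of the group's range. Wild type tumour 1 stood above the other wild type tumours in epithelial-mesenchymal genes (7.63, nearest 6.79), interstitial matrix genes (8.55, nearest 7.23), integrin and focal adhesion genes (6.61, nearest 6.24) and fibroblast markers (7.29, nearest 6.09), and below them in Dbh (6.49, nearest 8.12). Wild type tumour 5 stood below in basement membrane genes (5.77, nearest 6.41) and endothelial markers (5.00, nearest 5.76) and above in erythroid (5.26, nearest 4.77) and kidney tubule markers (3.71, nearest 3.65, a small gap at low signal). Wild type tumour 2 stood above in immediate early genes (7.52, nearest 6.74). Deficient tumours reached higher values than these in interstitial matrix (up to 8.70), erythroid (6.07), kidney tubule (3.80) and immediate early genes (7.83). Of 40 values tested, 10 had such a sample, and chance gives about 1 in 20 for a single value. The 40 values come from the same 7 tumours and some lists share genes. Most of the 10 came from wild type tumours 1 and 5, so the count cannot be set against that rate.

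By limma's test of the interaction the genotype difference differed between tissues for 58 genes, with Ddx4 at 1.10, Cd59a at 2.10, Trgv4 at -3.08, Podxl at -2.22 and Armcx2 at 0.94. In 38 of these genes, Ddx4 and Trgv4 included, both tumour groups had means under 5, where a genotype difference can go unseen.

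Genotype differences in bone marrow were weighed against sex and spread. In 29 of 29 arrays Xist and the Y-linked mean lay on opposite sides of their midpoints, and 7 deficient tumours had low Xist and high Y-linked signal, which argues against a genotype effect on these genes shared by both tissues. Both wild type marrow samples had the male pattern of these genes and all 3 deficient ones the female pattern, as animals of different sex would give. The labels give no sex, and genotype and this pattern cannot be told apart in marrow. Sex-biased expression shared with tumours predicted 0.00979 of the median size of the 58 interactions. The ratio was 0.0121 for the 20 genes with a tumour group mean of at least 5 and 0.00944 for the 38 of low tumour signal. Both tumour groups held both patterns, so a gene with such a bias has a wide spread in tumours and is hard to call. Xist itself had an interaction of 5.10 (SE 3.47, limma adjusted p = 0.798). Called genes were thus selected for a small slope in tumours, and at low signal a slope can also go unseen, so these ratios cannot decide. Sex-biased expression shared by both tissues stays open, as does a sex effect present in marrow alone. Of 616 X-linked genes, 40 had an unadjusted p under 0.05 in marrow, 6.49% against 3.95% elsewhere (Fisher's exact test, p = 0.0033, adjusted p = 0.066 over chromosomes). Of the interaction calls 5 were X-linked, 0.81% of these genes against 0.30% elsewhere (Fisher's exact test, p = 0.0447, adjusted p = 0.545). Neither share passed the adjustment. With no interaction and each tissue's own spread, 50 simulated data sets gave a median of 35 called genes (12 to 62), and the called genes had a median marrow to tumour SD ratio of 1.71 against 1.09 over all genes, so many of the 58 may come from a spread pooled with tumours. A genotype effect in marrow stays open as untested apart from sex.

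The lower Lancl1 probe set in deficient tumours was weighed next. Lower expression of the whole gene is argued against by the other probe set, at 0.19. Of 100 splits of the tumours, 1, the real one, gave as small a p over all probe sets, with a smallest limma p of 3.34e-07 in the others against 2.76e-09. This argues against chance, but 100 splits cannot show a share smaller than 1 of 100. Lancl1 lies 55 measured genes from Casp8, outside the 40 on each side of the planned test, and 0.679% of positioned probe sets lie as near, so sequence of the donor strain linked to the targeted allele, altering probe binding or the transcript's end, is a candidate explanation. It rests on position alone, and the labels name the same strain for all animals. The 80 genes nearest to Casp8 held 1.25% with an unadjusted p under 0.05 in tumours, against 3.19% elsewhere. That share rests on 1 probe set per gene and leaves out Lancl1, so it cannot speak for or against an effect at single probe sets. In wild type and deficient marrow the first probe set was at 4.31 and 4.30, a low signal, and the other at 7.73 and 8.36. Probe sequences and strain variants were not used here, and an effect of genotype on 1 transcript form stays open.

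Higher endothelial markers in deficient tumours were weighed last, and with the 3' minus 5' control signal as a covariate the difference was 0.39, which argues against RNA quality as the whole cause. Fewer tumour cells and more of every other cell type stay open: the endothelial minus macrophage mean, at 0.57 with an exact permutation p of 0.0111, and the endothelial minus T and NK cell mean, at 0.49 with one of 0.0211, go against them, but the first had a p of 0.0301 once the list of smallest p was chosen anew in each split and of 0.140 once the comparator was too, and neither passed without wild type tumour 5 (0.0536 and 0.107, at 0.37 and 0.29) or in the lower title series (0.400 and 0.442, at 0.34 and 0.21). Macrophage markers differed by -0.15 but by 0.028 without wild type tumour 1, and the endothelial minus fibroblast mean differed by 0.34 (exact permutation p = 0.101), by 0.18 without wild type tumour 1 (0.351), 0.44 without wild type tumour 2 (0.0400) and 0.39 without deficient tumour 16 (0.0479), while erythroid markers differed by 0.26 (median member -0.021) and chromaffin markers by -0.30 without passing. Without wild type tumour 5 the endothelial difference was 0.28, and it was 0.12 and 0.64 in the lower and higher title series, so how far that tumour or a batch behind the titles sets it stays open. Since the list failed the adjustment over 35 lists, chance stays open too, as does a wider change of stroma, with interstitial matrix genes at 0.33, and a genotype effect on vessels may be followed up only as a hypothesis.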

How the results depend on the processing

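Several alternatives here were chosen after seeing the data: covariates for matrix and macrophage genes, fits without 4 doubted tumours, without X and Y genes, lists within each title series, marrow-only and unadjusted counts, fry with mixed direction, and the splits of the samples. No paired analysis was possible because replicate numbers follow accession order and pair no samples. At an adjusted p under 0.05 limma's tumour count was 0 in each alternative run except the 1 call per probe set, and in all 24 fits without 1 tumour, while 583 genes had an unadjusted p under 0.05. As the real count was 0, all 100 of 100 splits of the tumours had to give as many (highest other 8), which carries no information. At an unadjusted p under 0.05, 77 of the 100 splits gave 583 genes or more, so chance cannot be excluded, and the highest other, 2541, points to a structure of the samples or to correlation between genes, which were not told apart. For tissue, 1 of 100 splits, the real one, gave as many (14063 in a 2-group fit, highest other 11246), which argues against chance as far as 100 splits can show. The marrow count of 4 became 2 with the mean of probe sets, 2 with the filter on dim genes (fewer genes tested), 0 without sex-linked genes, 9 per probe set, 83 in the 4-group model (sharing 0 of the 4), and 737 unadjusted. The 4-group model pools the spread with tumours of both Xist patterns. Xist had an SD of 3.90 in wild type and 3.86 in deficient tumours, against 0.77 and 0.31 in marrow. Such a spread makes the sex-linked genes fail there, and the 83 calls are open to a spread understated for marrow. For genes differing between tumours and bone marrow, the count became 9170 with the filter, 5347 with a 2-fold minimum and 31676 per probe set. For genes whose genotype difference differs between tumour and bone marrow, the count became 19 with the filter, 106 after quantile normalization again, 29 with the 2-fold minimum, 13 with array weights, 93 per probe set and 0 for marrow-only calls, and ran from 32 (without wild type marrow 1) to 422 (without wild type marrow 2). Tumour lists became 15 with camera at a preset correlation and 1 within the higher title series. Marrow lists became 0 with an estimated correlation, 0 with fry and 0 with fry mixed, and ran from 6 to 9 without 1 sample, 6 being without wild type marrow 2. Tissue lists became 15 and 5 with camera at preset and estimated correlation. The neighbourhood held 1 gene unadjusted. The cause was not tested for these unless given.

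Another Mycn probe set gave 0.034 in tumours. In the lower title number series Mycn was at 0.038, Th 0.13, Dbh 0.16, Col4a1 -0.14, Col18a1 -0.20, Col4a2 -0.068, Nid1 -0.090, Notch3 -0.068, Rgs5 -0.25, Bnip3 0.048, Ankrd37 0.24, Egln3 0.027 and Adm 0.43, and the basement membrane list was at -0.058, pericyte -0.17, hypoxia 0.079, interstitial matrix -0.14, cell cycle -0.024 (0.067 over all tumours), chromaffin 0.18 (-0.30), sympathoadrenal 0.070 (-0.043) and fibroblast -0.15 (0.079), while apoptosis genes were at 0.032 in the higher series, and the cause was not tested. With the median of the list neuronal differentiation genes list, tumours, deficient minus wild type, was at -0.017 and fibroblast markers list, tumours, deficient minus wild type, at -0.012. Without the 4 doubted tumours that neuronal list was at -0.025, apoptosis and death receptor genes list, tumours, deficient minus wild type, at 0.029, and skeletal muscle markers list, tumours, deficient minus wild type, at 0.050. With the mean of probe sets Dbh in marrow was at -0.069 and Bub1 at 0.40. Xist in tumours was at -0.12 with the Xist covariate, which removes it by construction. The value of the neural crest stem and pluripotency-linked genes list, tumour minus marrow, was 0.030 above other genes with a downward camera test at both correlations, and -0.098 with the mean of probe sets. Without 1 sample, Mycn ran from -0.082 to 0.0056 in tumours and -0.15 to 0.44 in marrow, and Th in marrow from -0.59 to 0.015. Among tumour lists neuronal genes ran from -0.022 to 0.044, apoptosis genes from -0.047 to 0.038 and macrophage markers from -0.24 to 0.028. Fibroblast markers ran from 0.0036 without wild type tumour 2 to 0.30 without wild type tumour 1, and cell cycle genes were at 0.031 without wild type tumour 6. Interactions ran from -0.24 to 0.10 for Casp8, -0.10 to 0.48 for Mycn and -0.17 to 0.43 for Th. In marrow, relative to other genes, interferon genes ran from -0.20 to 0.62 and granulocyte markers from -0.058 to 0.45. Leaving out 1 wild type marrow sample assumes that the other varies like the deficient ones. Of the other values for named genes and lists, 1782 kept direction and side of the threshold, 75 lost a call and 16 gained one. Without 1 sample, 3341 kept both and 16 lost a call. Several settings changed only the threshold, the variance model or the genes tested, so direction could not change there. As the main tests called no gene or list between tumour genotypes, keeping the side there means staying uncalled. These counts are thus no measure of how firm the results are. Low signal compresses differences of genes near the array's floor.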

Other observations

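The fit without 4 doubted tumours in this part was chosen after the data were seen.

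Muscle transcripts marked 3 tumours. The skeletal muscle list mean was 8.44 in deficient tumour 11, 7.66 in wild type tumour 3 and 6.68 in wild type tumour 7, against 4.86 or less in the other tumours. Adipocyte markers were graded over the tumours, from 5.10 in deficient tumour 9 to 7.67 in deficient tumour 7, 8.05 in wild type tumour 1 and 8.34 in deficient tumour 3. Macrophage markers ranged from 7.09 in deficient tumour 9 to 9.15 in wild type tumour 1, and interferon response genes reached 6.18 in wild type tumour 5. Markers of the adrenaline-producing chromaffin cell ranged from 7.48 in deficient tumour 16 to 9.24 in wild type tumour 6. None of these lists passed the permutation test between genotypes. Without the 3 muscle-rich tumours and wild type tumour 1, the endothelial list differed by 0.58 and still did not pass. That fit left out wild type tumours 1, 3 and 7 but kept wild type tumour 5, with the lowest endothelial mean, 5.00. With fewer wild type tumours that sample weighs more, so the larger difference does not make the result firmer.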
